A study of Saccharomyces cerevisiae BY4741 and Mus musculus with 8 samples.

How the data were processed

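Ribosome profiling sequences the short RNA fragments that ribosomes protect from nuclease digestion. The 8 libraries analysed here were 5 from Saccharomyces cerevisiae strain BY4741 grown as whole cultures and 3 from liver of C57BL6 mice, and the samples differed in the nuclease used for digestion, per the labels. In yeast, 2 libraries were made with RNase I and 1 each with RNase A, RNase T1 and RNase S7. In mouse liver, 1 library each was made with RNase T1, with RNase S7, and with RNases T1 and S7 together.

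Both deposited tables hold raw read counts, as whole numbers with a different total per library, and no normalization by the authors was seen in them. The submitters' processing notes name cutadapt, TopHat, Bowtie and HTSeq, without versions or roles, and give the mouse build GRCm38.p3 for every sample. A yeast build and the annotations used for counting are not given in the sources used here, nor is the strand setting of the counting. Without that setting, reads of a gene and of an overlapping gene on the other strand cannot be told apart. All columns of values in both tables were used.

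The yeast table had 5593 rows under systematic names, of which 116 joined the names of several genes, mostly paralogs, into 1 row. Of 5812 gene names in these rows, 5808 matched the R64 annotation of strain S288C (NCBI RefSeq), which served for gene symbols and coding sequences, and 1 symbol of the fixed gene lists had no match there. Since no yeast build was named, no yeast coordinates are given. The mouse table had 24058 rows under gene symbols, of which 22930 matched GENCODE M21, an annotation of GRCm38, and mouse coordinates are from that annotation. In the mouse table, 27 rows carried a date in place of a symbol, 2 dates occurred more than once, and these rows held 0.119% to 0.156% of a library's counts. Date rows were kept in the totals, and no gene was named from them.

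Yeast counts were filtered with filterByExpr, scaled by TMM and fitted with edgeR 4.0.16 (R 4.3.3) using 1 coefficient per nuclease over all 5 libraries. Each nuclease was compared with the RNase I pair by edgeR's quasi-likelihood test, 2-sided, with Benjamini-Hochberg adjustment over the 5130 rows that passed the filter and a threshold of 0.05. The installed version uses the legacy quasi-likelihood form by default. The fit had 1 residual degree of freedom, from the RNase I pair, so the single RNase A, T1 and S7 libraries were assumed to vary like that pair. The labels number the RNase I libraries as replicates without saying that they came from separate cultures. So p-values of single rows measure only the spread between these samples, which may be technical. With 1 library each for RNases A, T1 and S7, a difference of culture or preparation cannot be told apart from one of nuclease. Standard errors are approximate, the absolute log2 fold change divided by the square root of its quasi-likelihood F statistic. The fold changes used a prior count of 0.125. CPM values are relative to TMM-scaled library totals.

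Gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the other settings to try, apart from those said below to be added. The yeast lists were cytosolic ribosomal proteins, glycolysis and fermentation, mitochondrially encoded proteins, translation factors, ribosome biogenesis, nuclear-encoded respiratory chain and ATP synthase, mitochondrial ribosomal proteins, chaperones and heat shock, amino acid biosynthesis, proteasome, membrane transporters and cell wall proteins, histones, and non-coding RNAs of stable ribonucleoproteins. The last list had 0 rows in the yeast table. Yeast lists with at least 5 measured members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. With this preset, camera p-values rest on the spread among genes and not between libraries. They describe these libraries and not the nucleases in general. Camera with an estimated correlation was the alternative. Its correlations and its test rest on 1 residual degree of freedom, so it has little power and a call lost there says little. Shared calls between the 3 comparisons were set against 50 simulations and against independent lists. In each simulation all 5 libraries, RNase I included, were drawn anew without changes, and the comparisons shared the drawn RNase I libraries.

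With 1 library per nuclease, the mouse values had no replicate check and no test, and they describe these libraries and not the digestions in general. Rows with a mean of at least 20 CPM over the 3 libraries were kept, and log2 ratios of TMM-scaled CPM, relative to the counts in the kept rows, used a prior count of 0.5. Intervals of named ratios are exact 95% intervals of the Clopper-Pearson type from the counts of both libraries. Reads without molecular identifiers are not independent molecules, so these intervals cover counting error only. The mouse lists were secreted plasma proteins, complement, major urinary proteins, cytosolic ribosomal proteins, translation factors, mitochondrially encoded proteins, nuclear-encoded respiratory chain and ATP synthase, cytochrome P450 and xenobiotic metabolism, bile acid and cholesterol synthesis, urea cycle and amino acid catabolism, glycolysis and gluconeogenesis, fatty acid metabolism, selenoproteins, endoplasmic reticulum chaperones, histones, non-coding RNAs, and markers of Kupffer cells and macrophages, endothelial cells, stellate cells and fibroblasts, cholangiocytes, lymphocytes and neutrophils, and erythroid cells. The median of each list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins and not on base composition. Spearman correlations across genes related the log2 differences to the base composition and length of the coding sequence, with 500 bootstrap draws over genes in mouse. Genes are not independent replicates, so no p-value was attached to these.

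Named yeast genes were, per comparison, the 8 called rows with the largest increase and the 8 with the largest decrease that had a mean of at least 20 CPM over all 5 libraries and the same direction against each RNase I library, 2 members of each list with the largest absolute change, and the 5 most abundant rows with RNase I. Named mouse genes were chosen by size alone, in the same numbers, at a mean of at least 50 CPM, or 20 CPM for list members. Not every gene that the rule selected is printed. Genes named outside this rule are said to have been chosen after their values were seen. In the annotations, 30 of 103 named mouse genes had an exon overlapping another gene, and 3 of 73 named yeast rows overlapped another gene.

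The yeast test was checked on simulated counts for the real genes, with 200 changed. The changed genes were drawn only from rows above a minimum mean count, so recovery among rows with fewer counts was not measured. Of genes raised 2-fold, 94.0% were recovered in the simulated RNase A comparison, 96.0% for RNase T1 and 88.0% for RNase S7. Of genes lowered to 0.5-fold, 86.0%, 94.0% and 60.0% were recovered in the same order. Of unchanged genes, 0.246%, 0.368% and 0.143% were called. In the mouse self-test over 4403 rows, genes raised 2-fold in the simulated S7 library had a median log2 ratio of 1.02 against T1. Alternatives covered scaling by DESeq2 size factors or by library totals alone, other filters on low counts, the DESeq2 (version 1.42.0) Wald test, limma-voom, fits of only the RNase I libraries and the compared library, other prior counts, leaving out each RNase I library, and leaving out abundant gene groups. After the data were seen, leaving out the rows that join paralogs, the newer quasi-likelihood form, comparisons with no RNase I library in common and other settings for S7 minus T1 in yeast were added.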

Results

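Ribosome footprints were counted per gene in 8 libraries to compare ribonucleases for ribosome profiling, the use that the title of the series gives. RNase I cuts RNA after any base, RNase A cuts after pyrimidines, RNase T1 cuts after G, and RNase S7 (micrococcal nuclease) cuts preferentially next to A and U. The 5 yeast libraries, from strain BY4741, a laboratory strain derived from S288C, held 8711000 and 5342866 counts for RNase I replicates 1 and 2, 8210514 for RNase A, 14266277 for RNase T1 and 2767538 for RNase S7. The 3 mouse liver libraries held 5219012 counts for RNase T1, 5161558 for RNase S7 and 7491068 for RNases T1 and S7 together. In yeast the 10 most abundant rows took 23.1% and 21.6% of the counts with RNase I, 27.1% with RNase A, 32.6% with RNase T1 and 27.2% with RNase S7. In mouse liver the same share was 18.3%, 17.4% and 18.6% for T1, S7 and both.

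The RNase I pair gave the background for the yeast comparisons. Across the 5130 yeast rows tested, log2 CPM of replicates 1 and 2 correlated across genes with a Pearson r of 0.990 and a Spearman rho of 0.990, and the SD of their log2 ratio was 0.31. Between them 61 rows differed at least 2-fold, 13 higher and 48 lower in replicate 2. Their counts differed by more than sampling noise, with a chi-square statistic 9.25 times its degrees of freedom, and the coefficient of variation beyond counting was 9.80%. Some gene groups differed between the pair as well. The median log2 difference, replicate 2 minus replicate 1, was 0.95 for mitochondrially encoded proteins, -0.41 for the nuclear-encoded respiratory chain, 0.30 for ribosome biogenesis, -0.26 for mitochondrial ribosomal proteins and -0.23 for chaperones. For cytosolic ribosomal proteins it was 0.01.

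With RNase A, 52 of 95 cytosolic ribosomal protein rows rose against RNase I, as did 4 of 6 histone rows and 6 of 8 mitochondrially encoded rows. Of 45 membrane transporters and cell wall proteins, 9 fell and 3 rose. Among rows with a mean of at least 20 CPM and the same direction against each RNase I library, the largest increases by edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p; 1 library against 2) were in the row of COX1, the mitochondrially encoded cytochrome c oxidase subunit, joined with its intron-encoded genes (log2 fold change 2.18 ± 0.403 SE, adjusted p = 0.0068, from 15 and 32 counts with RNase I and 102 with RNase A) and in HOR7, a hyperosmolarity-responsive gene (1.89 ± 0.349, adjusted p = 0.0068). The COX1 row was 2.97 above replicate 1 and 1.34 above replicate 2. It stood at 1.47 and 5.08 CPM with RNase I and 13.3 with RNase A. Its mean over all 5 libraries passed 20 CPM only through RNase T1 (77.4) and RNase S7 (38.5). HOR7 itself differed between the RNase I libraries, at 33.9 and 12.4 CPM, with log2 differences of 1.39 and 2.82 from replicates 1 and 2. It lost its call with the DESeq2 Wald test, adjusted p = 0.363. The row YAR068W/HPF1/CSS1, which holds the cell wall mannoprotein gene HPF1, rose by 1.78 ± 0.121, the ribosomal protein row RPS10B/RPS10A by 1.75 ± 0.111, RCN2, a calcineurin regulator, by 1.73 ± 0.179, the vacuolar sorting receptor row VTH1/VTH2/YNR065C by 1.64 ± 0.167, RPL29 by 1.62 ± 0.115 and LSO1 by 1.51 ± 0.172, with adjusted p between 1.64e-05 and 0.000242. The row that joins the PAU seripauperin genes with DAN1, encoding cell wall mannoproteins, fell by 2.30 ± 0.368 (adjusted p = 0.00292; -2.70 and -1.65 against replicates 1 and 2), while PTR2, the di- and tripeptide transporter, fell by 2.20 ± 0.216 (adjusted p = 0.0001). Decreases were also called for the sterol importer AUS1 (-1.80), MYG1 (-1.54), the cell wall proteins TIP1 (-1.51) and TIR1 (-1.39), the mitochondrial carrier ODC2 (-1.41) and CCP1, cytochrome c peroxidase (-1.40 ± 0.331, adjusted p = 0.0261; -1.74 and -0.80 against replicates 1 and 2).

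Of 95 rows of cytosolic ribosomal proteins, 52 rose and 2 fell with RNase A, 57 and 4 when adjusted over the list alone, and the list median was 0.52 (camera adjusted p = 4.58e-21, or 0.566 with an estimated correlation). Of these, 39 rows join paralogs that were counted together, and all 39 rose. Of the 56 single-gene rows, 13 rose and 2 fell. Without the joined rows the median was 0.20, with a camera adjusted p = 0.00277. All 8 mitochondrially encoded rows were above RNase I, 6 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 2.78 that was 3.10 against replicate 1 and 2.03 against replicate 2 (camera adjusted p = 8.25e-08, or 0.601 with an estimated correlation). These genes had only 1 to 32 counts per RNase I library. Of 6 histone rows 4 rose, among them HTA2/HTA1 (1.26 ± 0.112, adjusted p = 5.47e-05) and HHT1/HHT2 (1.24 ± 0.110, adjusted p = 5.47e-05), 6 when adjusted over the list alone, with a median of 0.78 (camera adjusted p = 3.08e-07, or 0.795 with an estimated correlation). The 4 that rose all join paralogs, and the 2 single-gene histone rows had a median of 0.53 and no call. Of 45 membrane transporters and cell wall proteins 9 fell, TIR1 among them, and 3 rose, among them the mannoprotein CCW12 (1.12, adjusted p = 0.000209). Adjusted over the list alone 16 fell and 3 rose, and the median was -0.31 (camera adjusted p = 5.40e-06, or 0.601 with an estimated correlation). None of these list calls held with an estimated correlation, where the test rests on 1 residual degree of freedom and has little power. For ribosomal proteins that correlation was -0.0016, below the preset 0.01, so it does not account for the loss.

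The other lists did not pass camera with RNase A. Translation factors had 3 higher and 0 lower of 30 rows (3 and 0 adjusted over the list alone; median 0.05, or -0.02 without RNase I replicate 1), and the 3 that rose join paralogs, such as TEF2/TEF1, elongation factor 1 alpha (1.11 ± 0.0978), and TIF2/TIF1, initiation factor 4A (1.07 ± 0.108). Glycolysis and fermentation had 3 higher and 0 lower of 15 (4 and 1 adjusted over the list alone; median 0.07). They included TDH3/TDH2/TDH1, glyceraldehyde-3-phosphate dehydrogenase (0.80 ± 0.104, adjusted p = 0.000662), and PDC5/PDC1, pyruvate decarboxylase (0.64 ± 0.101, adjusted p = 0.00261), while HXK1 (-0.88), ENO1/ENO2 (0.34) and CDC19, pyruvate kinase (0.15), did not pass. Chaperones had 3 higher and 1 lower of 32 (3 and 1 adjusted over the list alone), with HSC82/HSP82 (0.94) and SSB1/SSB2 (0.78) higher. Their median was -0.05, or 0.14 without RNase I replicate 1, their mean 0.00 and the direction by camera was up. Amino acid biosynthesis had 5 higher and 3 lower of 54 (7 and 5 adjusted over the list alone; median 0.06), with LYS4 (-0.92) and ILV3 (-0.73) lower. The nuclear-encoded respiratory chain had 2 higher and 0 lower of 37 (2 and 0 adjusted over the list alone; median 0.10), ATP18 among them (0.77, its call lost under library totals alone), and ATP15 (0.67) did not pass. Proteasome genes had 1 higher, RPN9 (0.70), and 1 lower, PRE6 (-0.61), of 32 (2 and 4 adjusted over the list alone; median -0.11). RPN9 lost its call under library totals alone (adjusted p = 0.0644) and PRE6 with the DESeq2 Wald test (adjusted p = 0.0794). Mitochondrial ribosomal proteins had 0 higher and 3 lower of 68 (0 and 0 adjusted over the list alone; median -0.08, or 0.03 without RNase I replicate 1), including MRPS16 (-0.80) and MRPL8 (-0.79, or -0.98 and -0.51 against replicates 1 and 2). Both lost their calls with limma-voom (adjusted p = 0.0585 and 0.0587). Ribosome biogenesis had 0 higher and 1 lower of 49, NOG1 (-0.63; 0 and 0 adjusted over the list alone; median -0.14, or 0.04 without RNase I replicate 2), and CBF5 (-0.50) did not pass. NOG1 lost its call with the DESeq2 Wald test (adjusted p = 0.0547) and with limma-voom (adjusted p = 0.0553).

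In all, 416 of 5130 rows passed with RNase A, 255 higher and 161 lower, 1243 had an unadjusted p under 0.05, and 181 differed at least 2-fold (123 higher, 58 lower). Without the rows that join paralogs 263 were called, and by the DESeq2 Wald test 143. Scaling by library totals alone moved the median of all rows by -0.33, the share of calls that were higher from 61.3% to 8.37%, and the medians of amino acid biosynthesis, glycolysis, the respiratory chain and translation factors, and the value of CDC19, to below 0.

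With RNase T1, 55 of 95 ribosomal protein rows rose against RNase I and 10 fell. All 6 histone rows rose, as did 8 of 15 glycolytic rows, 11 of 30 translation factors and 7 of 32 chaperones. These counts include rows that join paralogs. Of the transporters and cell wall proteins 13 of 45 fell, and of mitochondrial ribosomal proteins 11 of 68. By edgeR's quasi-likelihood test the COX1 row rose by 4.72 ± 0.320 (adjusted p = 3.14e-06, 867 counts with RNase T1; 5.49 and 3.86 against replicates 1 and 2). TMA7, a ribosome-associated protein, rose by 2.38 ± 0.136 (adjusted p = 1.58e-06), HTZ1, the histone variant H2A.Z, by 1.95 ± 0.166 (adjusted p = 1.90e-05), and the joined rows RPS14A/RPS14B by 1.85 ± 0.106, ENA5/ENA2/ENA1, sodium pumps, by 1.80 ± 0.120, RPL1B/RPL1A by 1.76 ± 0.104, VTH1/VTH2/YNR065C by 1.72 ± 0.165 and RPL15A/RPL15B by 1.71 ± 0.107. The PAU row fell by 2.63 ± 0.368 (adjusted p = 0.000622; -3.03 and -1.98 against replicates 1 and 2), ERD2, the receptor that retains proteins in the endoplasmic reticulum, fell by 2.12 ± 0.187 (adjusted p = 2.35e-05) and PTR2 fell by 2.06 ± 0.208 (adjusted p = 4.92e-05). RPS30B (-1.96), AUS1 (-1.96), YMR317W (-1.94), the cell wall protein TIR3 (-1.93) and IZH4, a membrane protein of zinc homeostasis (-1.80), fell with adjusted p between 2.04e-05 and 0.00053. RPS30B has a near-identical paralog, RPS30A, in a row of its own, so the split of reads between them is uncertain.

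Of the 95 ribosomal protein rows 55 rose and 10 fell with RNase T1 (63 and 11 adjusted over the list alone), with a median of 0.56 (camera adjusted p = 3.60e-17) that was 0.19 without joined rows (camera adjusted p = 0.00351). This call did not hold with an estimated correlation (adjusted p = 0.477), nor did that of any other list. Of the joined rows 35 of 39 rose, and of the single-gene rows 20 rose and 10 fell. All 6 histone rows rose (6 adjusted over the list alone; median 1.0), with HHT1/HHT2 at 1.51 ± 0.109. Of 15 glycolysis rows 8 rose and 0 fell (10 and 1 adjusted over the list alone; median 0.46), including TDH3/TDH2/TDH1 (1.33 ± 0.103), ENO1/ENO2 (1.19 ± 0.105), PDC5/PDC1 (1.0) and CDC19 (0.43 ± 0.103, adjusted p = 0.0132). Of 30 translation factor rows 11 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.28), including TEF2/TEF1 (1.64) and EFT2/EFT1, elongation factor 2 (1.32). Of 32 chaperone rows 7 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.23), including SSB1/SSB2 (1.24) and HSC82/HSP82 (1.02). Apart from CDC19, every row named here for glycolysis, translation factors and chaperones joins paralogs. Without the joined rows the medians were 0.36 for glycolysis, 0.20 for translation factors and 0.23 for chaperones. Of 54 amino acid biosynthesis rows 15 rose and 1 fell (18 and 3 adjusted over the list alone; median 0.17), with ARG8 at 1.04 and LYS4 at -1.05. The 8 mitochondrially encoded rows had 5 higher and 0 lower (5 and 0 adjusted over the list alone; median 1.82, or 2.10 against replicate 1 and 1.23 against replicate 2). Transporters and cell wall proteins had 2 higher and 13 lower of 45 (2 and 13 adjusted over the list alone; median -0.15), with TIR1 at -1.46 and PDR5, a drug efflux pump, at -1.06. PDR5 lost its call with the DESeq2 Wald test, adjusted p = 0.132. Mitochondrial ribosomal proteins had 4 higher and 11 lower of 68 (4 and 12 adjusted over the list alone; median -0.26, or -0.36 against RNase I replicate 1 and -0.05 against replicate 2), with MRPL4 at -0.98 and RSM26 at -0.87.

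These 9 lists passed camera with RNase T1, with adjusted p from 3.60e-17 to 0.0213. With an estimated correlation, adjusted p = 0.848 for mitochondrial ribosomal proteins, 0.486 for translation factors and 0.477 for the other 7. Proteasome genes had 6 higher and 1 lower of 32 (6 and 1 adjusted over the list alone; median 0.17; camera adjusted p = 0.0726, or 0.0339 without joined rows), with PUP1 at 0.90 and RPN12 at -0.71. PUP1 lost its call under library totals alone. The nuclear-encoded respiratory chain had 6 higher and 4 lower of 37 (7 and 5 adjusted over the list alone), with COX12 at 1.13, ATP15 at 1.0, a median of 0.08, or -0.13 without RNase I replicate 2, and a mean of -0.00. ATP15 lost its call with the DESeq2 Wald test (adjusted p = 0.0521) and under library totals alone. Ribosome biogenesis had 7 higher and 4 lower of 49 (8 and 4 adjusted over the list alone; median 0.07, or -0.07 without RNase I replicate 1), with NOG2 at 0.65 and RIX1 at -0.74. NOG2 lost its call under library totals alone (0.06), and RIX1 with the DESeq2 Wald test (adjusted p = 0.116). NOG2 overlaps the small nucleolar RNA gene SNR191 on its own strand, so its value is uncertain.

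In all, 1037 rows passed with RNase T1, 558 higher and 479 lower, 1784 had an unadjusted p under 0.05, and 305 differed at least 2-fold (161 higher, 144 lower). The DESeq2 Wald test called 311. Under library totals alone the median of all rows moved by -0.58 and the share of calls that were higher from 53.8% to 4.02%, CDC19 went to -0.16, and the medians of ribosomal proteins (-0.02), glycolysis (-0.13), translation factors (-0.31), chaperones (-0.35), amino acid biosynthesis (-0.41), proteasome, ribosome biogenesis and respiratory chain fell below 0.

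With RNase S7, 7 of 8 mitochondrially encoded rows rose against RNase I, as did 3 of 6 histone rows, all of which join paralogs. Of ribosome biogenesis rows 11 of 49 fell, and of mitochondrial ribosomal proteins 11 of 68. By edgeR's quasi-likelihood test the COX1 row rose by 3.72 ± 0.398 (adjusted p = 0.000213; 4.49 and 2.86 against replicates 1 and 2), HOR7 by 2.54 ± 0.360 (adjusted p = 0.00102; 2.03 and 3.46 against replicates 1 and 2), the HPF1 row by 2.04 ± 0.122 (adjusted p = 8.75e-06). The cell wall protein SED1 rose by 2.04 ± 0.173 and CCW12 by 1.76 ± 0.124. As with RNase A, HOR7 lost its call with the DESeq2 Wald test, adjusted p = 0.130. RCN2 (1.79), RPL29 (1.64) and HMRA1 (1.61) rose as well. HMRA1 is the silent mating-type copy of the a1 gene and shares its sequence with the active copy of a-type strains, so its reads are uncertain. Among rows with a mean of at least 20 CPM RPS30B had the largest decrease and fell by 4.61 ± 0.313 (adjusted p = 1.35e-05, 8 counts with RNase S7), and its paralog RPS30A fell by 1.88 ± 0.239 (adjusted p = 0.0005). CGR1 (-2.63) and FAF1 (-1.63), which act in ribosomal RNA processing, YDL085C-A (-2.36), the mitochondrial ribosomal protein MRPL51 (-1.91), PTR2 (-1.75) and ODC2 (-1.74) fell with adjusted p between 0.000556 and 0.00288. MRPL51 overlaps another annotated reading frame on the opposite strand.

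The 8 mitochondrially encoded rows had 7 higher and 0 lower (8 and 0 adjusted over the list alone), with a median of 3.67 (camera adjusted p = 4.28e-08) that was 3.97 against replicate 1 and 2.78 against replicate 2. With an estimated correlation this call and those of the other lists with RNase S7 did not hold, with adjusted p = 0.753 for each list that had passed. Histones had 3 higher and 0 lower of 6 (3 and 0 adjusted over the list alone; median 0.49; camera adjusted p = 0.00937), including HTA2/HTA1 (1.35) and HHT1/HHT2 (0.95), and the 3 that rose join paralogs. The single-gene histone rows had a median of 0.10. Ribosome biogenesis had 0 higher and 11 lower of 49 (0 and 14 adjusted over the list alone; median -0.27; camera adjusted p = 0.000919), including RLP24 (-1.11) and LTV1 (-0.95). Its median was -0.08 against replicate 1 and -0.40 against replicate 2. Mitochondrial ribosomal proteins had 2 higher and 11 lower of 68 (2 and 20 adjusted over the list alone; median -0.21; camera adjusted p = 0.00381), including MRPS16 (-1.38), with medians of -0.31 and -0.06 against the same replicates. Transporters and cell wall proteins had 3 higher and 6 lower of 45 (3 and 10 adjusted over the list alone; median -0.21; camera adjusted p = 0.0362), with CCW12 among the higher and TIR1 (-1.43) among the lower, and this call ended without joined rows (adjusted p = 0.0816).

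Ribosomal protein rows went both ways with RNase S7. Of 95 rows, 33 rose and 17 fell (43 and 22 adjusted over the list alone), with a median of 0.23 and a mean of 0.12 (camera adjusted p = 0.00274). Of the joined rows 25 of 39 rose and 0 fell, and of the 56 single-gene rows 8 rose and 17 fell. Without the joined rows the median was -0.13 and the call ended (camera adjusted p = 0.107), and under library totals alone it was -0.02. The other lists did not pass camera. Translation factors had 3 higher and 4 lower of 30 (3 and 6 adjusted over the list alone; median -0.03), with TEF2/TEF1 at 0.95 and TIF11, initiation factor 1A, at -1.15. The 3 translation factor rows that rose join paralogs. Glycolysis had 3 higher and 1 lower of 15 (3 and 2 adjusted over the list alone; median 0.12), with PDC5/PDC1 at 0.82 and TDH3/TDH2/TDH1 at 0.70, and HXK1 (-0.94) and ENO1/ENO2 (0.22) did not pass. The glycolytic CDC19 (0.36, edgeR quasi-likelihood adjusted p = 0.0403) passed, but not under library totals alone (0.11, adjusted p = 0.494) or with the DESeq2 Wald test at about the same fold (0.37). Amino acid biosynthesis had 9 higher and 4 lower of 54 (9 and 6 adjusted over the list alone; median 0.11), with SER1 at 0.89 and LYS4 at -1.21. LYS4 lost its call with the DESeq2 Wald test (adjusted p = 0.0771). Chaperones had 1 higher, HSC82/HSP82 (0.68), and 2 lower, including AHA1 (-0.83, DESeq2 Wald test adjusted p = 0.0557), of 32 (1 and 2 adjusted over the list alone; median -0.14, or 0.03 without RNase I replicate 1). Proteasome genes had 2 higher and 4 lower of 32 (2 and 6 adjusted over the list alone; median -0.11), with RPN9 at 0.90 and RPN13 at -1.24. The nuclear-encoded respiratory chain had 5 higher and 0 lower of 37 (5 and 1 adjusted over the list alone; median 0.08, or -0.01 without RNase I replicate 2), with ATP15 at 1.16, and COX9 (-0.90) did not pass.

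In all, 629 rows passed with RNase S7, 335 higher and 294 lower, 1458 had an unadjusted p under 0.05, and 364 differed at least 2-fold (174 higher, 190 lower). The DESeq2 Wald test called 202. Under library totals alone the median of all rows moved by -0.26, the share of calls that were higher went from 53.3% to 15.7%, and the medians of glycolysis, amino acid biosynthesis and the respiratory chain, and the value of ENO1/ENO2, fell below 0. This was the shallowest yeast library, and on simulated counts it recovered 60.0% of genes lowered to 0.5-fold, all drawn from rows above a minimum mean count.

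**Figure D1:**
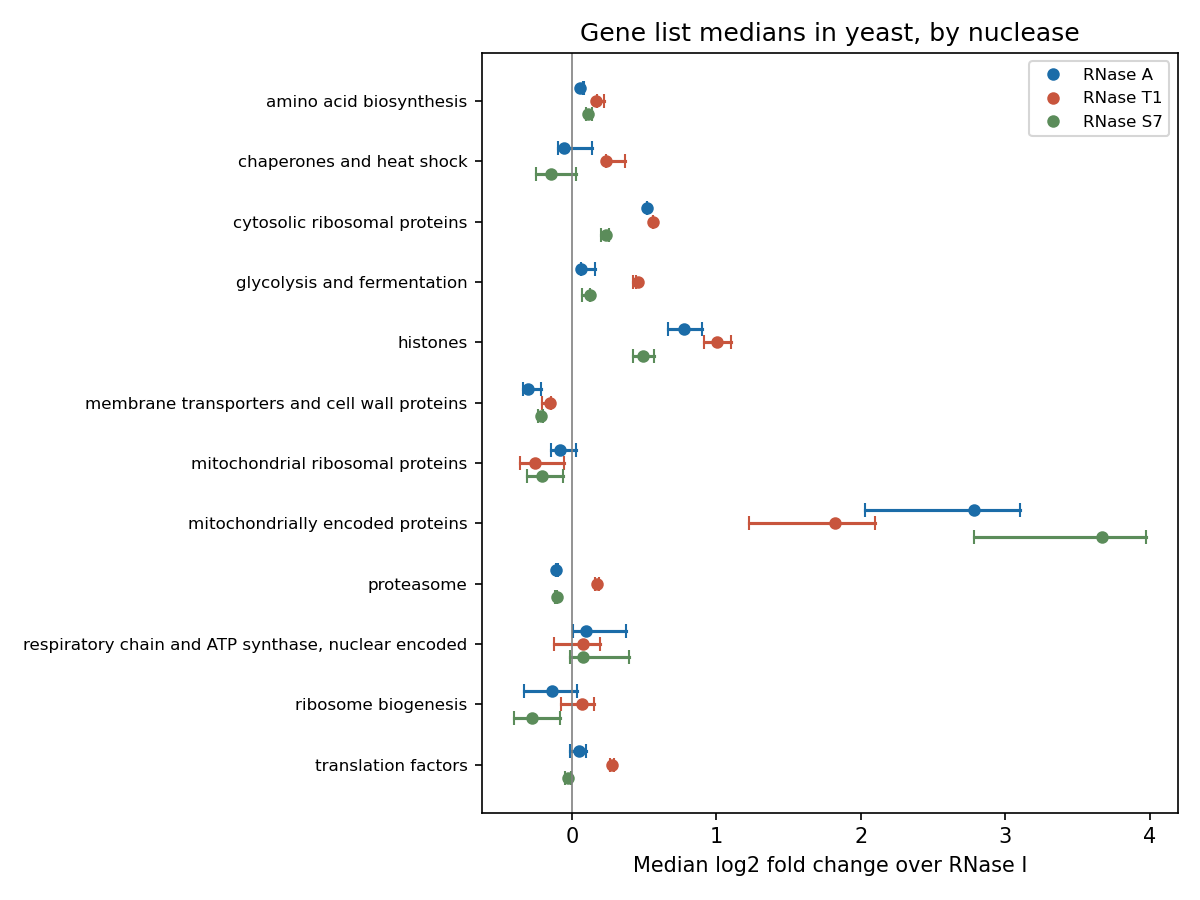
Median log2 fold change of each yeast gene list against RNase I for RNases A, T1 and S7, with dots for the fit and line ends for the medians against RNase I replicate 1 and replicate 2. The mitochondrially encoded list lies highest with RNase S7, at 3.67, and the ribosomal protein medians of 0.52, 0.56 and 0.23 include the rows that join paralogs, the last turning to -0.13 without them, while under library totals alone the T1 and S7 medians go to -0.02.

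Calls overlapped between the 3 comparisons. RNases A and S7 shared 174 rows higher and 84 lower, with 1 in opposite directions, against 16.7 and 9.23 for independent lists of these sizes. RNases A and T1 shared 136 higher and 62 lower, with 14 opposite, against 27.7 and 15.0. RNases T1 and S7 shared 127 higher and 53 lower, with 70 opposite, against 36.4 and 27.5. In simulations without changes, where the RNase I libraries were drawn anew as well, at most 1 row was shared in each direction, with means up to 0.1. Few rows are called at all when nothing changes, so this is no background for overlap among the real calls. Fold changes correlated across genes with a Pearson r of 0.681 for A and S7 (simulated 0.231), 0.434 for A and T1 (simulated 0.339) and 0.253 for T1 and S7 (simulated 0.248), and their covariances were 0.199, 0.118 and 0.0903 against simulated values of 0.0205, 0.0201 and 0.0208. With no RNase I library in common, 1 comparison against replicate 1 and the other against replicate 2, r was 0.585 and 0.529 for A and S7, 0.330 and 0.289 for A and T1, and 0.167 and 0.163 for T1 and S7. The covariances were then 0.155 and 0.147, 0.0829 and 0.0760, and 0.0526 and 0.0518. This split was chosen after the data were seen, and a deviation that both RNase I libraries have in common stays in it. Called in all 3 comparisons were 93 higher rows, 49 of them joining paralogs, and 35 lower rows, 1 of them joined. Among the higher were RCN2, RPL29, HOR7 and the COX1 and HPF1 rows, and among the lower were PTR2, AUS1, TIR1, TIP1, LYS4, RPS30B and the PAU row. Without reference to RNase I, the libraries of A and S7 correlated across genes with a Spearman rho of 0.983, and those of T1 and S7 with 0.948, where 595 rows differed at least 2-fold.

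Fold changes in yeast followed the base composition of the coding sequence, across genes. The Spearman rho with the share of G was 0.408 for RNase T1, -0.403 for RNase S7 and -0.309 for RNase A, against -0.0747 between the RNase I replicates. With the share of C plus U it was -0.228 for T1, 0.321 for S7 and 0.0138 for A (0.0150 between replicates), the last turning to -0.0182 over rows with a mean of at least 20 CPM. With A plus U it was -0.228, 0.0681 and 0.154 (0.184 between replicates). With coding length it was -0.152, 0.0161 and -0.103, smaller in size than the 0.347 between the RNase I replicates, and it moved with the control library. Without RNase I replicates 1 and 2 in turn, it was -0.242 and -0.0751 for T1, -0.0754 and 0.0902 for S7, and -0.206 and -0.00482 for A. With A plus U the same settings gave -0.269 and -0.183 for T1, 0.0163 and 0.106 for S7, and 0.0753 and 0.204 for A. These were 4 relations per comparison, and none was tested, since genes are not replicates.

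In mouse liver, the library made with RNase S7 had more counts than the RNase T1 library for several RNAs of nuclear ribonucleoproteins and a vault RNA. It also had more for most cytochrome P450 and xenobiotic genes. Fewer counts were seen for most Kupffer cell markers and for transcripts such as Ptma and Chchd2. Rn7sk, the RNA that holds the elongation factor P-TEFb inactive (GRCm38 chromosome 9, 78175303 to 78175633), had a log2 ratio of 3.24 (95% counting interval 3.02 to 3.49). Rmrp, the RNA of RNase MRP (chromosome 4, 43492783 to 43493063), stood at 3.04 (2.70 to 3.40), Rpph1, the RNA of RNase P (chromosome 14, 50807449 to 50807767), at 3.01 (2.73 to 3.32) and the vault RNA Vaultrc5 (chromosome 18, 36801866 to 36802008) at 1.86 (1.75 to 1.97). The annotated Rmrp overlaps an exon of Ccdc107 on the opposite strand and Rpph1 an exon of Ccnb1ip1 on its own strand, so their reads are uncertain. Rnf13 was at 1.74 (1.52 to 1.97). Lower with S7 were Ptma, prothymosin alpha (-1.55, -1.72 to -1.38), Chchd2, a mitochondrial protein (-1.49, -1.62 to -1.36), the mitochondrial ribosomal protein Mrps21 (-1.49), Hsbp1 (-1.29), Timm13, a mitochondrial import chaperone (-1.18), Tex264 (-1.15) and the histone Hist1h4d (-1.13). The major urinary protein genes, near-identical paralogs clustered on chromosome 4, went both ways, with Mup7 (1.96), Mup17 (1.75), Mup16 (1.56) and Mup20 (1.20) higher and Mup1 (-3.26) and Mup12 (-2.58) lower, and the division of reads among them is uncertain.

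Cytochrome P450 and xenobiotic genes were higher with S7 in 32 of 42 rows, with a median of 0.30 at percentile 100 among random lists of matched level, and Cyp2c50 (1.37, 1.30 to 1.45) and Cyp3a25 (1.35, 1.23 to 1.47) leading. The random lists were not matched on the share of G, which S7 minus T1 followed across genes (Spearman rho -0.512). Base composition may therefore enter this and the other percentiles. Bile acid and cholesterol genes were higher in 19 of 28 (median 0.19, percentile 99.0), with the cholesterol enzyme Sc5d at 1.15 and the bile acid transporter Slc10a1 at 0.86. The 5 non-coding RNAs had a median of 3.01 (percentile 100), and 4 were higher. The 9 major urinary protein rows had a median of 1.20 (percentile 100), with 5 at least 2-fold higher and 2 at least 2-fold lower. Respiratory chain and ATP synthase genes were higher in 20 of 58 (median -0.14, percentile 0.560), although Cox6c (1.41) and Cox7a2 (1.15) were far higher. Kupffer cell markers were higher in 2 of 8 (median -0.35, percentile 1.1), with the complement genes C1qb (-0.46, -0.68 to -0.25) and C1qc (-0.46) lowest. The percentiles of the other lists lay between 11.6 and 86.4. They were cytosolic ribosomal proteins (median 0.03, with Rpl39 at 1.41 and Rpl14 at 1.17), complement (0.04, with C1ra at 0.61), secreted plasma proteins (median 0.04, mean -0.02, with Serpina1a at 0.87 and Saa2 at -1.22), urea cycle (0.02, or -0.01 under library totals alone, with Ass1 at 0.57 and Cbs at -0.50), translation factors (median -0.00, mean 0.01, with Eif3e at 0.59 and Eif1 at 0.56), selenoproteins (-0.00, with Sepw1 at -0.97 and Dio1 at -0.39), fatty acid metabolism (-0.02, with Thrsp at -0.55 and Acadvl at -0.46), endoplasmic reticulum chaperones (-0.07, with Spcs1 at 0.60 and Sdf2l1 at -0.52), glycolysis and gluconeogenesis (-0.09, with Tpi1 at -0.48 and Gapdh at -0.43), histones (-0.17, with Hist1h2bc at -1.90 and H2afv at -0.50), stellate cell and fibroblast markers (-0.07, with Col1a1 at -1.08 and Ecm1 at -0.58) and endothelial markers (-0.16, with Stab1 at -0.26 and Stab2 at -0.25). Of the most abundant transcripts, albumin (Alb) was at -0.12, Apoe at -0.74, Trf at -0.34 and Serpina3k at 0.17. Of the remaining cell markers, 0 lymphocyte and neutrophil genes, 1 cholangiocyte gene (Spp1, 0.05) and 2 erythroid genes (Alas2, 0.61; Hbb-bs, 0.20) passed the level minimum, and mitochondrially encoded genes had 0 rows in the table. Of 4403 rows, 50 were at least 2-fold higher and 44 at least 2-fold lower, and the libraries correlated across genes with a Spearman rho of 0.930.

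**Figure D2:**
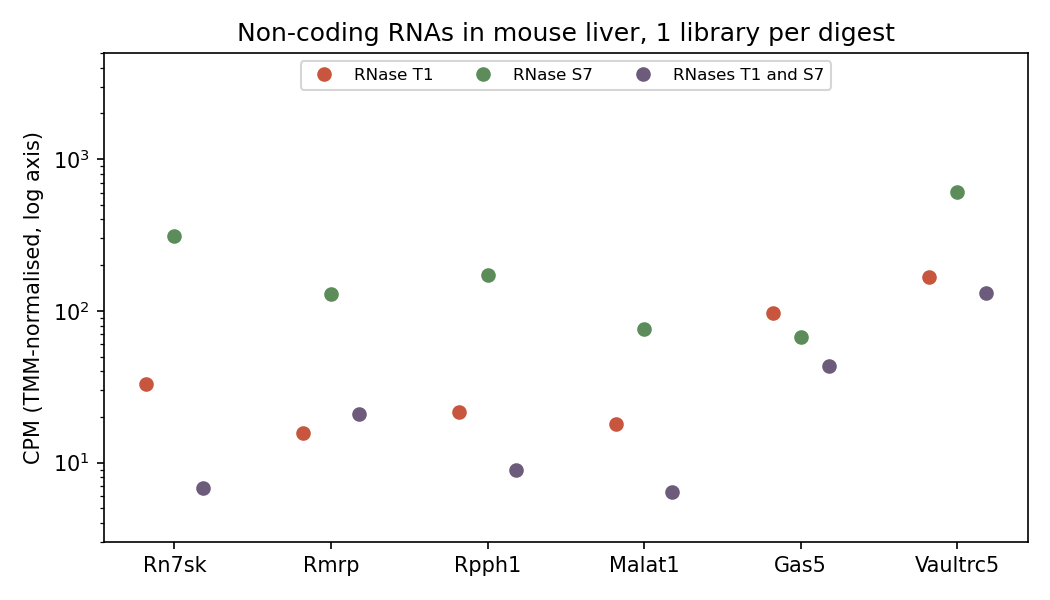
CPM, on a log axis, of Rn7sk, Rmrp, Rpph1, Malat1, Gas5 and Vaultrc5 in the mouse liver libraries digested with RNase T1, RNase S7 or both, 1 library each. Rn7sk stands at 32.9, 312 and 6.83, and all but Gas5 are highest with RNase S7.

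Digestion with RNases T1 and S7 together gave a mouse liver library closer to the T1 library than the S7 library was. Against T1, 4 of the 5 non-coding RNAs were lower and Rmrp, chosen after its values were seen, was higher (0.42), with Rn7sk at -2.25 (95% counting interval -2.76 to -1.80), the nuclear RNA Malat1 at -1.48 (-2.04 to -0.96), Rpph1 at -1.25 (-1.73 to -0.79) and Gas5, a host of small nucleolar RNAs, at -1.18 (-1.39 to -0.97). Mup17 (1.60), Mup7 (1.43), Mup16 (0.98) and Mup20 (0.84) were higher and Mup1 (-0.92) lower, with Adtrp (1.13), Sec61g (1.01), 2010107E04Rik (1.39) and 2810007J24Rik (0.97) also higher. Rnf5 (-0.86), the ribosomal protein Rpl37 (-0.78), Mrfap1 (-0.75) and Hnrnpa0 (-0.74) were lower. Cytochrome P450 genes were higher in 32 of 42 (median 0.19, percentile 99.99), again with Cyp2c50 (0.81) and Cyp3a25 (0.81), while selenoproteins were higher in 2 of 12 (median -0.25, percentile 0.230), with Dio1, the thyroid hormone deiodinase, at -0.60 and Gpx4 at -0.47. Kupffer cell markers were higher in 2 of 8 (median -0.28, percentile 1.03), with C1qb at -0.64 and C1qa at -0.53. The list medians were 0.56 for major urinary proteins (percentile 100) and -1.25 for non-coding RNAs (percentile 0). Histones stood at -0.19 (percentile 3.51; H3f3a -0.55, H3f3b -0.43), the respiratory chain at -0.06 (percentile 3.07; Cox7a2 0.70, Ndufs7 -0.59), stellate cell markers at -0.23 (percentile 5.42; Col1a1 -0.67, Col3a1 -0.54), ribosomal proteins at -0.06 (percentile 7.44; Rpl39 1.52), endoplasmic reticulum chaperones at 0.10 (percentile 93.6; Spcs1 0.58, Sdf2l1 -0.55) and secreted plasma proteins at 0.11 (percentile 93.0; Serpind1 0.60, Serpina1a 0.60). The medians of bile acid (0.03; Sc5d 0.80, Nsdhl 0.63), complement (0.08; Hc 0.39), endothelial (-0.12; Clec4g -0.35, Kdr -0.21), fatty acid (-0.01; Acaa1b -0.54, Acaa1a -0.53), glycolysis (-0.00; Khk -0.50, Pgam1 -0.33), translation factor (0.03; Eif4e 0.60, Eif6 -0.55) and urea cycle genes (-0.00; Ftcd -0.46, Gnmt -0.40) had percentiles between 16.8 and 74.8, and under library totals alone the bile acid and translation factor medians were both -0.02. Alb was at 0.17, Apoe at -0.34, Serpina3k at 0.19 and Trf at -0.01. Of 4403 rows, 9 were at least 2-fold higher and 5 at least 2-fold lower, a higher share of 64.3% that was 43.8% under library totals alone, and the Spearman rho was 0.962.

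Against RNase S7, the library made with both nucleases was lower in the non-coding RNAs and higher in several coding transcripts, among them Ptma and Chchd2. Rn7sk was at -5.50 (95% counting interval -5.96 to -5.10), Rpph1 at -4.26 (-4.66 to -3.90), Rmrp at -2.62 (-2.89 to -2.36) and Vaultrc5 at -2.21 (-2.32 to -2.11), and Atp6v0c (-1.55), Slc25a39 (-1.30), Tmem38b (-1.30) and Pxmp2 (-1.11) were lower as well. The annotated Tmem38b overlaps a ribosomal RNA gene on its own strand, so its value is uncertain. Mup1 (2.34), Mup12 (1.91), Ptma (1.61), Chchd2 (1.41), Hsbp1 (1.13), Mrps21 (1.07), Anapc13 (0.98), the detoxifying enzyme Gstp1 (0.94, 0.91 to 0.98) and Polr2l (0.91) were higher. Secreted plasma proteins were higher in 36 of 54 (median 0.12, percentile 99.8), with the acute phase genes Saa2 (0.85) and Saa1 (0.57), and the respiratory chain in 37 of 58 (median 0.09, percentile 97.5), with Ndufb10 at 0.83 and Cox6c at -0.90. Bile acid genes were higher in 9 of 28 (median -0.12, percentile 0.780; Hsd3b7 -0.49, Baat -0.37), cytochrome P450 genes in 16 of 42 (median -0.08, percentile 0.955; Cyp2c68 -0.71), selenoproteins in 2 of 12 (median -0.18, percentile 0.890; Gpx4 -0.65, Sepw1 0.55) and ribosomal proteins in 35 of 79 (median -0.04, percentile 3.02; Rpl14 -1.29, Rpl36 -1.05). The non-coding RNA median was -3.54 (percentile 0). Major urinary proteins had a median of -0.36 (percentile 0.03) but a mean of 0.17, with Mup20 at -0.36. The histone median was -0.12 and its mean 0.02 (percentile 8.65; Hist1h2bc 1.75, H3f3a -0.91). The remaining medians, with percentiles between 12.7 and 94.7, were 0.10 for endoplasmic reticulum chaperones (Hsp90b1 0.37, P4hb 0.30), 0.04 for glycolysis (Gapdh 0.68, Khk -0.37), 0.04 for translation factors (Eif3e -0.49, Eif1ax 0.47), 0.05 for Kupffer cell markers (C1qa -0.57, Ctss 0.45), 0.04 for fatty acid metabolism (Acaa1b -0.49), 0.01 for complement, -0.01 under library totals alone (Mbl1 -0.60, C1ra -0.45), -0.03 for the urea cycle (Ass1 -0.37, Cbs 0.34), -0.03 for endothelial markers (Stab2 0.23, Stab1 0.20) and -0.02 for stellate cell markers (Col1a1 0.41, Col3a1 -0.40), and the means of the Kupffer cell, fatty acid, complement and endothelial lists, at -0.00, -0.00, -0.00 and 0.00, had the other sign. Alb was at 0.29, Apoe at 0.40, Trf at 0.32 and Serpina3k at 0.02. Of 4403 rows, 8 were at least 2-fold higher and 22 at least 2-fold lower, with a Spearman rho of 0.956. Of all 4403 rows, the library made with both lay between S7 and T1 for 2126 and nearer to T1 for 2180. Of the 94 rows at least 2-fold apart between S7 and T1 it lay between for 83, which choosing rows far apart favours. It was nearer to T1 for 20 of the 50 that were higher with S7 and for 33 of the 44 that were lower.

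S7 and T1 were compared with each other in both organisms. Across genes, the log2 difference S7 minus T1 had a Spearman rho with the share of G of -0.636 in yeast and -0.512 in mouse liver (95% bootstrap interval -0.535 to -0.488). For both nucleases together against T1 in mouse it was -0.627 (-0.647 to -0.608), and against S7 it was 0.0876 (0.0591 to 0.116). At a mean of at least 5 CPM the last was 0.0262, outside this interval. With A plus U the rho of both nucleases against T1 was 0.609 in mouse, and that of S7 minus T1 was 0.235 in yeast and 0.380 in mouse, with C plus U 0.426 and 0.120, and with coding length 0.134 and 0.149. Median differences of gene groups, yeast first, were -0.43 and 0.03 for cytosolic ribosomal proteins, -0.35 and -0.00 for translation factors, 0.16 and -0.14 for the nuclear-encoded respiratory chain, -0.45 and -0.17 for histones, and -0.43 and -0.09 for glycolysis. Under library totals alone the yeast medians were -0.10 for ribosomal proteins, -0.02 for translation factors, 0.49 for the respiratory chain, -0.12 for histones and -0.11 for glycolysis. These are values of 1 library each and had no test.

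**Figure D3:**
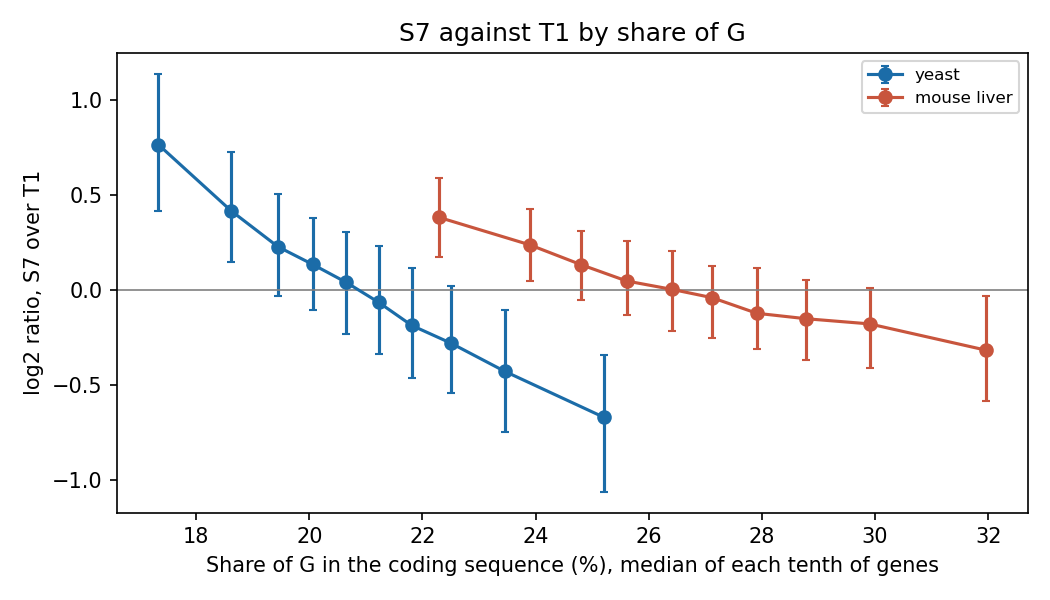
Median log2 difference, RNase S7 minus RNase T1, by decile of the share of G in the coding sequence, for yeast and mouse liver, with bars for the quartiles. In yeast the median goes from 0.76 in the lowest decile, at 17.3% G, to -0.67 in the highest, at 25.2% G, and in mouse liver from 0.38 at 22.3% to -0.32 in the highest.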

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

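The checks of joined against single-gene ribosomal protein rows, of chance deviations of the RNase I libraries and of library depth were chosen only after the result was seen. No biological explanation was tested for the patterns here, because the design varies the nuclease and gives no biological groups. A difference between cultures, animals or preparations cannot be told apart from one between nucleases that have a single library.

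The median difference between RNases S7 and T1 had opposite signs in the 2 organisms for 2 gene lists. For cytosolic ribosomal proteins the median log2 difference, S7 minus T1, was -0.43 in yeast and 0.03 in mouse liver, 0.47 higher in mouse. For the nuclear-encoded respiratory chain it was 0.16 in yeast and -0.14 in mouse liver, a difference of -0.30. These depend on the scaling, since under library totals alone the yeast medians were -0.10 for ribosomal proteins, which narrows the gap, and 0.49 for the respiratory chain, which widens it. With 1 library per nuclease, these differences were not tested, and the lists have members on both sides. Above 0 were 28 of 95 yeast and 41 of 79 mouse ribosomal protein rows, and 20 of 37 yeast and 20 of 58 mouse respiratory chain rows. The mouse ribosomal protein median lay within the range of random lists (-0.09 to 0.08), so it shows no direction there.

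Most yeast rows that join paralogs were higher with RNases A, T1 and S7 than with RNase I. Of 106 such rows tested, 75, 81 and 62 were called higher in that order. Called lower were 1, 2 and 2, the PAU row each time. Among ribosomal proteins the joined rows exceeded the single-gene rows by a median of 0.75 (bootstrap interval 0.59 to 0.95) with A, 0.82 (0.67 to 1.12) with T1 and 0.78 (0.46 to 1.03) with S7. This is the observation that raised the question of reads shared between paralogs, so it does not test that explanation, which stays open. Joined rows outside that list exceeded single-gene rows of the nearest level with RNase I by 0.79 (0.62 to 0.93), 0.93 (0.67 to 1.08) and 0.77 (0.57 to 0.94). This argues against a high expression level, as measured with RNase I, as the whole cause. If RNase I understated the joined rows, their matches were too low, so level is not excluded. The most abundant rows with RNase I, such as TDH3/TDH2/TDH1, join paralogs and had no single-gene row at their level. If shared reads had been counted for a part of the copies in the RNase I libraries, rows of 3 or more genes would exceed rows of 2. They did by 0.18 (-0.10 to 0.60), an interval that holds 0, so this form of the explanation cannot be told apart from others with 23 and 83 rows.

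In yeast, fold change followed the share of G in the coding sequence, up with RNase T1 and down with RNase S7. Expression level was argued against, because within 5 level classes the median rho of S7 minus T1 was -0.686 (lowest -0.702, highest -0.499). Chance deviations of the RNase I libraries do not enter S7 minus T1 directly, where rho was -0.636 (-0.653 to -0.618). This sign followed from the opposite signs already seen for T1 and S7, so it is no separate test. The interval is over rows and leaves out chance deviations of the single T1 and S7 libraries. A candidate explanation is the cleavage preference of the nucleases for bases, which predicted the same sign in mouse liver, where rho was -0.512 (-0.535 to -0.487). With A plus U, S7 minus T1 had a rho of 0.235 in yeast and 0.380 in mouse liver, and both nucleases against T1 had 0.609 in mouse liver. RNase S7 against RNase I had 0.0681, against 0.184 between the RNase I replicates. RNase A, which cuts after pyrimidines, had 0.0138 with C plus U and -0.309 with G. These values do not all follow from the preferences as known, so the explanation stays open.

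In mouse liver, Rn7sk, Rmrp, Rpph1 and Malat1 were highest with RNase S7 and lower in both libraries digested with RNase T1. As a check of library depth, the S7 library held 0.989 times the counts of the T1 library. This could not test depth as a cause, since the scaled ratios already leave library totals out. At their share of G, the trend of coding genes gave the 5 non-coding RNAs log2 ratios from -0.43 (Rpph1) to -0.003 (Gas5). The RNAs lay a median of 8.79 residual SD above that trend (from -1.45 for Gas5 to 9.26 for Rpph1). Their ratios had already been seen, so this excess is no separate test. It shows only that the trend of coding genes does not give ratios of this size. That trend may not hold for non-coding RNAs. Rpph1, at 33.9% G, also lay above the interval of 19.8% to 30.9% G of the coding genes. The share of G in the transcript is therefore not excluded as a cause. Digestion of these RNAs outside ribosomes may differ between the nucleases, and this was not tested.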

How the results depend on the processing

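Leaving out the rows that join paralogs, the newer quasi-likelihood form, comparisons with no RNase I library in common and other settings for S7 minus T1 in yeast were tests chosen only after the result was seen. The cause was not tested for any change below, except where fewer genes or samples entered.

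Genes called went from 416, 1037 and 629 for RNases A, T1 and S7 to 1470, 3308 and 1124 under library totals alone (123, 133 and 176 of them higher) and to 143, 311 and 202 by the DESeq2 Wald test. For RNase A they were 637 with DESeq2 size factors and 263 without the rows that join paralogs. The newer quasi-likelihood form called 407, 1056 and 552. With an estimated correlation 0 gene lists passed camera for A, 0 for T1 and 0 for S7. That test rests on 1 residual degree of freedom and has little power, so these losses say little about the lists. An RNase I library left out leaves no residual degrees of freedom, so those settings gave values with no test.

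Under library totals alone, medians turned in RNase T1 to -0.41 for amino acid biosynthesis, -0.35 for chaperones, -0.019 for cytosolic ribosomal proteins, -0.13 for glycolysis and -0.31 for translation factors, CDC19 to -0.16, and in RNase S7 ribosomal proteins to -0.021. Of genes not called, CDC19 in RNase A turned to -0.18 and ENO1/ENO2 in RNase S7 to -0.040. The yeast medians of S7 minus T1 moved to -0.10 for ribosomal proteins, -0.024 for translation factors, 0.49 for the respiratory chain and -0.11 for glycolysis. Without the rows that join paralogs the S7 median of ribosomal proteins was -0.13.

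Yeast rows at least 2-fold apart numbered 66, 130 and 132 at a mean of at least 20 CPM, 359, 493 and 571 with no filter on low counts, and 990 for T1 under library totals alone. Mouse rows at least 2-fold apart for S7 against T1, both against T1 and both against S7 numbered 230, 68 and 131 at a mean of at least 5 CPM and 51, 7 and 14 at 50 CPM. Apart from library totals, these settings change which genes are kept.

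Spearman correlations with RNase I ranged without RNase I replicate 1 or 2 from 0.974 to 0.978 for A, 0.965 to 0.969 for T1 and 0.962 to 0.964 for S7, and were 0.953, 0.940 and 0.931 at a mean of at least 20 CPM. Mouse correlations at 5 CPM were 0.958, 0.975 and 0.968.

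The relation to the share of G without replicate 1 or 2 ranged from -0.328 to -0.249 for A, 0.387 to 0.409 for T1 and -0.418 to -0.360 for S7, and was 0.463 for T1 at 20 CPM. For C plus U these settings gave -0.221 to -0.219 for T1 and 0.300 to 0.324 for S7. For T1 it was -0.252 at 20 CPM, -0.240 without ribosomal protein and glycolysis genes and -0.247 without joined rows, and for A -0.0182 at 20 CPM. In mouse at 5 CPM, S7 against T1 gave -0.434 for G and 0.308 for A plus U, both against T1 gave -0.554, 0.549 and -0.0741 for C plus U, and both against S7 gave 0.0262 for G and 0.123 for A plus U. The spread that these yeast values were set against came from the same pair of RNase I libraries, so closeness to it says little about stability.

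Of 112 values of named yeast genes, direction and side of the threshold were the same for 106 with DESeq2 size factors, 99 under library totals alone, 108 with limma-voom, 110 at 20 CPM, 110 with no filter and 109 in fits of only the RNase I libraries and the compared library. With the DESeq2 Wald test 10 lost their call, 74 did not change and the rest had no adjusted p. Settings for values other than counts were not run, since the tables held counts. Pearson correlations of fold changes with no RNase I library in common went from 0.681 to 0.585 and 0.529 for A and S7, from 0.434 to 0.330 and 0.289 for A and T1, and from 0.253 to 0.167 and 0.163 for T1 and S7. No paired analysis was possible because the compared groups share fewer than 2 replicate numbers. Of the yeast libraries RNase S7 was the shallowest, at 2767538 counts, and in the simulated comparisons it recovered the smallest share of genes lowered to 0.5-fold.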
